A study of Mus musculus with 36 samples.

How the data were processed

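The series holds 36 samples of mouse embryonic stem cells (ESCs) and of neural stem cells (NSCs) derived from them, wildtype (WT) or with all 3 TET dioxygenase genes knocked out (TKO). The ESCs are male V6.5 cells of mixed 129/C57BL/6 background. Per the labels, ESCs were separated from feeder cells by preplating for 45 minutes and kept on gelatin in serum and LIF for 24 hours, and NSCs were harvested on day 6 after 1 passage. RNA-seq of 10 samples, with 3 WT and 2 TKO lines in each cell type, and promoter capture Hi-C (pcHiC) of 1 WT and 1 TKO NSC sample were analysed here. The 4 bisulfite sequencing and 20 CUT&Tag samples were not analysed here.

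Per the submitters' processing notes, the tools used on the RNA-seq samples included Trim Galore 0.6.5, STAR 2.7.3a, featureCounts and DESeq2 1.40.2, with the mm10 build. The deposited RNA-seq values are a signal that is never negative: read counts per gene divided by size factors of DESeq2, per the labels, in 1 table per cell type. Each table was normalized on its own by the authors, so that levels of the separate tables were not compared directly. Within each library the values were whole multiples of 1 step, between 0.918 and 1.08, and 100% of values came out as whole reads within a tolerance of 1e-06. The recovered reads summed to between 41.0 M and 49.1 M per library, against 20 M to 30 M stated in the labels. Between 75.2% and 82.7% of the values of up to 20 reads were even numbers, as counts of both mates of a pair would be, and divided by 2 the totals come to 20.5 M to 24.5 M. The lowest total of any listed gene over the 5 libraries of a table was 51 reads. Column names matched the sample descriptions, and 0 columns were left unused.

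For pcHiC, the deposited lists give 2 anchor fragments and a score for each loop. The score is the authors' own value per loop, was at least 5 in both lists, and served only to describe or filter loops. The loop caller and the rule for the minimum are not given in the sources used here. Loops between captured fragments can be listed in both directions.

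Gene symbols were matched to the GRCm38.p6 reference annotation (mm10): of 19426 genes in either table, 17657 matched by symbol, 69 by a synonym and 1700 did not match, so that 91.2% have a position. The table of genes gives no strand, so a gene was assigned to a captured fragment that holds either end of its annotated span. Coordinates are 1-based on mm10. Whether reads were counted by strand is not given in the sources used here, so reads of overlapping antisense genes, like those of near-identical copies such as the Xlr3 and Zscan4 genes, may not be told apart.

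TKO and WT were compared within each table with limma 3.58.1 (trend) on log2(value + 1), for genes with a mean of at least 10, two-sided, with Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The labels carry a separate code for each of the 3 WT and 2 TKO samples of a cell type. These are called lines here and taken as the replicates. Whether the WT codes stand for separate lines or for cultures of 1 line cannot be told from the codes. With 2 lines in 1 arm the p-values rest on the spread pooled over both arms. Whether the TKO effect differed between NSCs and ESCs was tested as an interaction over 15381 genes of both tables, in which the scaling of each table cancels. For NSCs against ESCs within a genotype, the recovered reads of all 10 libraries were scaled together by the median of ratios and tested in the same way. Overlaps of calls were tested with Fisher's exact test. The direction of 29 gene lists was tested with camera at a preset correlation of 0.01 and adjusted over the lists with at least 5 measured members. The same test with an estimated correlation, and fry, which asks whether a list's genes move on balance one way, were run beside it. For loops no test was made, since there is 1 library per genotype. Genes with fewer, equal or more loops in TKO were compared by their median log2 fold change with 10000 random lists of the same size, matched on mean expression in 20 bins.

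The lists covered DNA methylation machinery, naive and core pluripotency, primed epiblast, neural stem cells and radial glia, astroglia, oligodendroglia, neurons, forebrain, mid-hindbrain and spinal, and dorsoventral patterning, neural crest, mesoderm, endoderm, trophoblast and epithelium, fibroblasts and mesenchyme, endothelium with blood and microglia, 2-cell-like genes, germline genes silenced by methylation, imprinted genes, Wnt targets and inhibitors, Notch, Nodal with Lefty and BMP, interferon and antiviral genes, antigen presentation, cell cycle, p53 and apoptosis, stress and RNA quality, clustered protocadherins, and extracellular matrix and adhesion. Genes were named by a fixed rule. It takes the Tet genes and a set of methylation, pluripotency and neural genes, and per cell type the 10 largest changes in each direction. Those had to pass the test, with every TKO library on one side of every WT library, a mean of at least 50 and an established symbol. From each list it takes up to 4 called members with the largest change, or, if none was called, 2 members with the highest mean. It also takes the 5 largest interactions in each direction, and the 5 genes with the largest gain and the largest loss of loops. The groups, tests, lists, naming rule and most alternatives were set before the data were examined.

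The alternatives were other pseudocounts, filters, scalings and thresholds, a robust fit, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, a block for replicate or line, all 10 libraries in one fit, and leaving out each library in turn. Those chosen after seeing the data were edgeR on reads divided by 2, bounds and intervals with both mates of a pair counted as 1 (reads halved per library and rounded up), leaving out chromosomes 8 and 11 and chromosome 6 from 100 Mb on (called distal 6 here), and centring each library on the median of each chromosome. Chromosome medians and shares of genes higher were taken over genes with a mean of at least 100, and the centring over genes whose mean log2 value corresponds to at least that. The same line codes stand in the labels of the ESC and NSC samples, and those libraries were paired by code. WT codes hold only a replicate number, so that the pairing of WT lines is an assumption. Deviations of same-line libraries from their group means correlated at -0.036 to 0.046 across genes, and no call count of the NSC-ESC comparisons moved by over 1.5 times with a line block.

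No pair of replicate libraries agreed within sampling noise: chi-square per degree of freedom of their reads was 8.97 to 24.0. The fits were tested on simulated counts with known fold changes. At true folds of 1.5, 2, 4 and 8, the ESC fit (16667 genes) recovered 52%, 88%, 94% and 100% of 50 changed genes each, the NSC fit (17447 genes) 58%, 78%, 98% and 96%, and the interaction fit (15375 genes) 18%, 78%, 96% and 100%. False calls made up 3.47%, 8.84% and 6.41% of the calls. Far fewer genes were changed in the simulations than were called in the data, so these shares need not hold there. Where a group had 0 reads of a gene, its fold is given as a lower bound against 3 reads per library, and with 1 to 3 reads in the group as a ratio with its exact 95% interval. Shares have exact 95% binomial (Clopper-Pearson) intervals. Floors and intervals cover counting error only, as PCR reads without molecular identifiers are not independent molecules. Computations ran under R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.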

Results

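Gene expression was measured by RNA-seq in wildtype (WT) mouse embryonic stem cells (ESCs), in ESCs lacking the TET dioxygenases (TKO), and in neural stem cells (NSCs) derived from both, with 3 WT and 2 TKO lines per cell type. Lines are samples with separate codes in the labels, and those of WT may be cultures of 1 line. TET enzymes oxidize 5-methylcytosine in DNA, and the series asks what they do in NSC specification. The libraries held 44.2 M, 42.2 M and 42.0 M reads (WT) and 41.0 M and 44.4 M reads (TKO) in ESCs, and 45.1 M, 42.8 M and 46.9 M (WT) and 49.1 M and 45.8 M (TKO) in NSCs. Values below are normalized counts, given as mean ± SD with n = 3 WT and n = 2 TKO lines, and log2 fold changes are TKO over WT with their standard error (SE) and the adjusted p of limma. Chromatin contacts of promoters were mapped by promoter capture Hi-C (pcHiC) in 1 WT and 1 TKO NSC library.

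The targeted genes were examined first in each library. In ESCs, Tet1 (chromosome 10, 62804570 to 62887469, mm10) was at 12237, 10599 and 9633.6 in WT and at 4634.8 and 4965.8 in TKO, and fell by 1.17 on the log2 scale (SE 0.10, adjusted p = 2.45e-06). Tet2 (chromosome 3, 133463677 to 133545136) was at 2892.9, 2437.9 and 2156.2 in WT and 1700.3 and 1660.7 in TKO (-0.56, SE 0.12, adjusted p = 0.00513). This call was lost without TKO replicate 2, which gave the highest of its adjusted p over all alternatives (0.0595). Tet3 on chromosome 6 was at 433.03, 331.76 and 487.22 in WT and at 203.24 and 150.89 in TKO (-1.23, SE 0.23, adjusted p = 0.00163). In NSCs, Tet3 was at 4049.9, 4088.9 and 4208.5 in WT against 2378.6 and 2596.6 in TKO (-0.73, SE 0.07, adjusted p = 1.60e-05). Tet1 in NSCs was at 663.44, 716.66 and 901.33 against 517.04 and 573.77 (-0.47, SE 0.15, adjusted p = 0.0320). This call was lost in 6 settings, among them without WT replicate 2 or 3 or either TKO replicate, with adjusted p of up to 0.179. Tet2 did not pass in NSCs (1276.2, 1294.8 and 1066.4 in WT, 1146.1 and 1555.4 in TKO, adjusted p = 0.459), and so gave no check of the labels there. Counts per gene include reads outside any deleted exons, so that a level above 0 in TKO does not measure functional transcript.

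**Figure D1:**
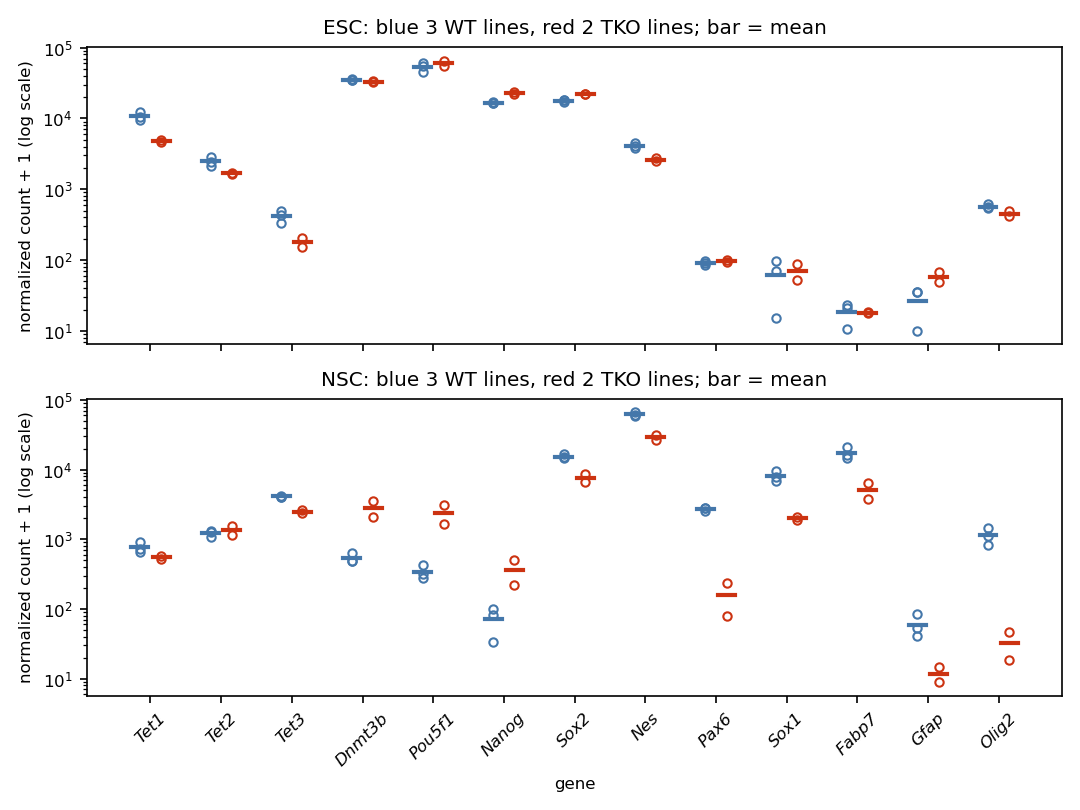
Normalized counts plus 1 (log scale) of 13 genes in each ESC library (top) and NSC library (bottom); blue circles are the 3 WT lines, red circles the 2 TKO lines and bars the group means. Tet1 and Tet3 were lower in every TKO library, and in NSCs Pax6 averaged 2747 in WT and 156 in TKO while Pou5f1 averaged 341 and 2347.

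The first comparison asked what loss of the TET enzymes changed in undifferentiated ESCs. Strc, which encodes stereocilin of inner ear hair bundles, rose from 1.34 ± 2.32 to 3242 ± 693 (log2 10.87, SE 0.69, adjusted p = 3.48e-07). Slc15a2, a peptide transporter gene, fell from 347 ± 18.1 to 4.19 ± 5.93 (-6.83, SE 0.67, adjusted p = 9.29e-06). Fgf8, a growth factor of gastrulation and brain patterning, fell from 829 ± 103 to 141 ± 80.2 (-2.66, SE 0.27, adjusted p = 1.20e-05), and Sp5, a transcription factor induced by Wnt signals, fell from 760 ± 130 to 138 ± 21.2 (-2.45, SE 0.20). Foxa2, an endoderm and floor plate transcription factor, fell from 320 ± 25.1 to 67.0 ± 5.84 (-2.24, SE 0.25, adjusted p = 3.24e-05). The pluripotency factor Pou5f1 did not pass the test (53352 ± 7477 in WT, 60125 ± 7697 in TKO, adjusted p = 0.286).

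Among the other genes of the largest increase, Slc5a4b, of a sodium and glucose cotransporter family, rose from 42.8 ± 5.11 to 304 ± 79.3 (2.78, SE 0.34), and Usp26, an X-linked deubiquitinase gene of the germline, from 128 ± 19.8 to 971 ± 673 (2.73, SE 0.33). Pnma5, also X-linked, rose by 2.65 (SE 0.28), and Mfap5, a microfibril component on distal 6, by 2.54 (SE 0.35). Xlr3b (3.49), Pramel7 (2.77), Xlr3a (2.66), Trim16 on chromosome 11 (2.60, and 2.21 with chromosomes centred) and Megf11 (2.44) rose as well. Without TKO replicate 2 none of these 5 passed, with adjusted p of 0.209, 0.0603, 0.319, 0.0647 and 0.0536, each the highest over its alternatives. Xlr3a then stood at 1.65, and Pramel7 was also lost without TKO replicate 1. Among the genes of the largest decrease, Cer1, a secreted inhibitor of Nodal and BMP signals, fell from 80.8 ± 21.4 to 8.29 ± 9.01 (-3.56, SE 0.70, and -2.35 without TKO replicate 2), and Trim67 from 699 ± 64.8 to 82.1 ± 29.1 (-3.12, SE 0.23). Trim67 lies on chromosome 8 and stood at -2.70 with chromosomes centred, and Lhx1, given below, lies on chromosome 11. Cyp26a1, which degrades retinoic acid, fell from 199 ± 29.5 to 34.2 ± 19.8 (-2.62, SE 0.39), and the lymphotoxin gene Ltb and the G protein gene Gna14 changed by -2.80 and -2.36. Olig3 (-2.53) and Lhx1 (-2.50), transcription factors of neural and mesodermal patterning, lost their call without TKO replicate 2 (adjusted p = 0.0639 and 0.0716, the highest over their alternatives), where Lhx1 stood at -1.59. Of 17033 genes tested in ESCs, 2437 passed, 1242 higher and 1195 lower in TKO, of which 208 and 246 changed by at least 2-fold. With equal totals 1158 were higher and 1292 lower. Without chromosomes 8, 11 and distal 6, and here and below also without genes that have no position, it was 602 and 704. The first principal component (39.9% of variance) separated TKO from WT libraries. Without TKO replicate 2 the count was 1066 and without WT replicate 2 it was 1609.

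Part of the ESC changes followed chromosomes. Genes of chromosome 11 had a median difference from the WT mean of 0.25 and 0.53 (log2) in the TKO libraries, and genes of distal 6 of 0.55 and 0.48, while genes of chromosome 8 stood at -0.40 and -0.42. Chromosome 11 held 440 of the higher calls (35.4%), distal 6 another 131 (10.5%), and chromosome 8 held 359 of the lower calls (30.0%). These 3 regions held 14.3% of tested genes and 39.6% of calls. Without them, and without the genes that have no position, 1306 genes were called. With each library centred on its chromosome medians 1588 were called, and both settings were chosen after seeing the data. The 3 regions held 579 of the higher and 386 of the lower calls, fewer than the first setting took away. The fall to 1306 is therefore not due to the regions alone. In NSCs the same medians were 0.53 and 0.54 for chromosome 11 and 0.52 and 0.54 for distal 6, but -0.0085 and -0.050 for chromosome 8.

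**Figure D2:**
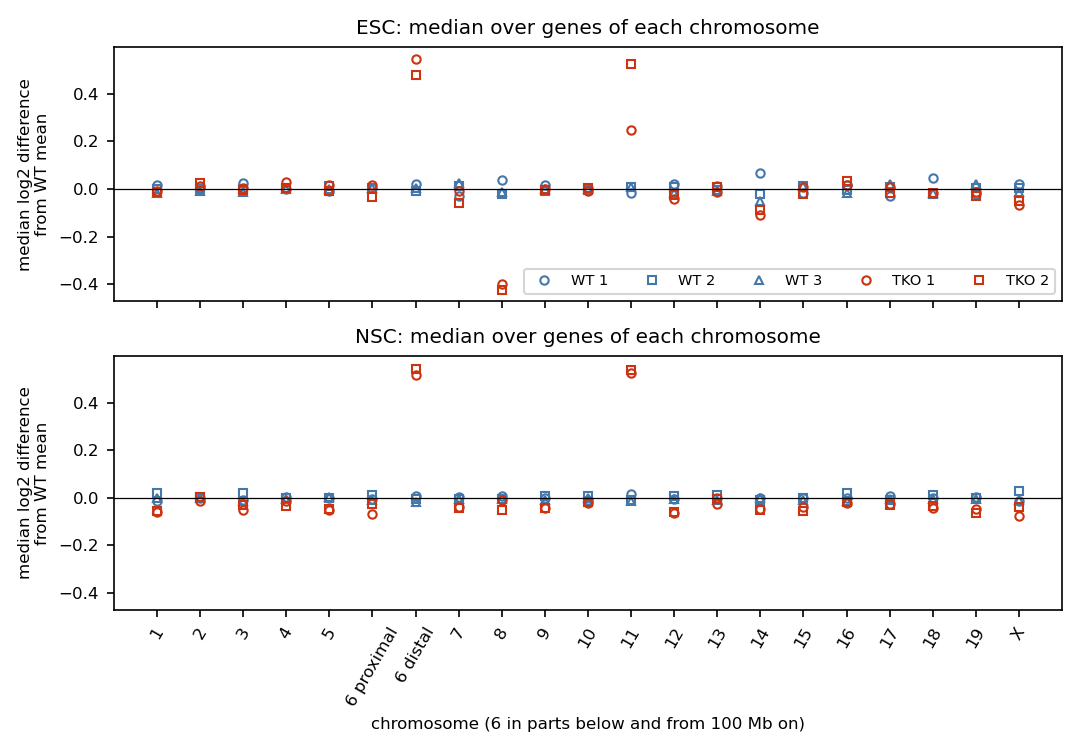
Median over genes of the log2 difference from the WT mean, per chromosome (x axis; chromosome 6 in parts below and from 100 Mb on) and library, in ESCs (top) and NSCs (bottom); blue symbols are WT and red symbols TKO libraries. Chromosome 11 and distal 6 lay between 0.25 and 0.55 in the TKO libraries, and chromosome 8 at -0.40 and -0.42 in TKO ESCs.

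No list of early developmental genes was called in ESCs, though members of each passed. Of 11 primed epiblast genes, 2 rose and 5 fell (2 and 5 adjusted over the list alone; list adjusted p = 0.225). Fgf15 fell from 549 ± 87.0 to 147 ± 16.8 (-1.88, SE 0.21), the epiblast growth factor Fgf5 changed by -1.41 (SE 0.22) and Car14 by -1.19 (SE 0.23), whereas the Wnt effector Lef1 rose by 0.86 (SE 0.15). Of 25 naive and core pluripotency genes, 9 rose and 3 fell (9 and 3 adjusted over the list alone; list adjusted p = 0.226). Nanog, which lies on distal 6, rose from 16489 ± 301 to 22825 ± 1170 (0.47, SE 0.07, adjusted p = 0.000472). With chromosomes centred it stood at -0.04 (adjusted p = 0.758, the highest over its alternatives). Fgf4 fell by 0.68 (SE 0.09) and Klf2, on chromosome 8, by 0.54 (SE 0.07). The first call was lost with all 10 libraries in one fit (adjusted p = 0.114) and the second with chromosomes centred (adjusted p = 0.226), in each case the highest over the alternatives. Sox2 rose by 0.30 (SE 0.07). This call was lost without TKO replicate 2 or WT replicate 2, with adjusted p of up to 0.0632, and 0.0634 over its alternatives. None of 16 mesoderm genes rose and 6 fell (0 and 6 adjusted over the list alone; list adjusted p = 0.226). The primitive streak gene T changed by -1.60 (SE 0.37), and by -2.63 without TKO replicate 1. Without TKO replicate 2 it stood at -0.57 and the call was lost (adjusted p = 0.152, and up to 0.243 over its alternatives). Among 15 trophoblast and epithelial genes, 1 rose and 5 fell (1 and 5 adjusted over the list alone; list adjusted p = 0.360). The T-box factor Eomes stood at -1.50 (SE 0.20) and the keratin Krt8 at -1.01 (SE 0.16). The median of this list was slightly above 0 (0.0063) while its mean (-0.11) and test were negative.

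No neural list was called in ESCs by camera or fry. Of 23 neural stem and radial glia genes, 2 rose and 3 fell (2 and 3 adjusted over the list alone; list adjusted p = 0.635), with a median above 0 (0.04) against a mean (-0.06) and test below it. The intermediate filament gene Nes fell from 4127 ± 318 to 2614 ± 164 (-0.66, SE 0.10, adjusted p = 0.000384) and the cadherin Cdh2 by 0.97 (SE 0.20). Pax6, Sox1, Fabp7, Gfap and Olig2 did not pass, with adjusted p from 0.201 to 0.972. Tubb3, the neuronal tubulin on chromosome 8, fell by 0.61 (SE 0.10), lost with chromosomes centred (adjusted p = 0.218, the highest over its alternatives). Of 18 neuronal genes, 0 rose and 5 fell (1 and 5 adjusted over the list alone; list adjusted p = 0.226), among them Gad1, for GABA synthesis, at -1.82 (SE 0.27) and the RNA-binding Elavl3 at -1.22 (SE 0.19). Of 11 dorsoventral and 15 mid-hindbrain and spinal patterning genes, 3 and 4 fell and none rose (0 and 3, and 0 and 5, adjusted over the list alone; list adjusted p = 0.226 and 0.360), and none of 8 forebrain genes passed (0 adjusted over the list alone; list adjusted p = 0.580).

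In the DNA methylation machinery, 2 of 17 genes rose and 4 fell in TKO ESCs (3 and 4 adjusted over the list alone; list adjusted p = 0.580). The de novo methyltransferase Dnmt3a rose from 8532 ± 73.5 to 11589 ± 1086 (0.44, SE 0.08, adjusted p = 0.00178), while Dnmt1 (adjusted p = 0.562) and Dnmt3b (adjusted p = 0.472) did not pass. Of 24 germline genes silenced by methylation, 4 rose and 1 fell (6 and 2 adjusted over the list alone; list adjusted p = 0.226). Tex19.1 on chromosome 11 rose from 1622 ± 423 to 5540 ± 2213 (1.75, SE 0.21) and Tuba3a on distal 6 by 1.65 (SE 0.20). Among 30 imprinted genes, 2 rose and 7 fell (5 and 9 adjusted over the list alone; list adjusted p = 0.226). Grb10, a growth restrainer on chromosome 11, changed by -2.05 (SE 0.29), lost under a robust fit (adjusted p = 0.147, the highest over its alternatives). It stood at -2.91 without TKO replicate 1 and at -1.20 without TKO replicate 2. Zrsr1, on chromosome 11, rose by 1.46 (SE 0.16) and Mcts2 by 0.88 (SE 0.16). The list of stress and RNA quality genes was the only one called in ESCs by camera, with 1 of 19 members higher and 12 lower (1 and 13 adjusted over the list alone; list adjusted p = 1.89e-05, and adjusted p = 0.659 with an estimated correlation). By fry, which tests whether a list's own genes move one way, it missed the threshold (adjusted p = 0.0527), and the imprinted list, lower on balance, was the only one called (adjusted p = 0.0419). The immediate early gene Fos fell from 5900 ± 173 to 3432 ± 71.7 (-0.78, SE 0.09), Junb on chromosome 8 changed by -0.92 (SE 0.12), Atf3 by -1.07 (SE 0.20) and Chac1, a target of the integrated stress response, by -0.90 (SE 0.17). Genes that respond to sample handling therefore moved with genotype in the ESCs, beside the groups described above. The number of lists called was 4 without TKO replicate 1 and 5 without TKO replicate 2. Of 27 cell cycle genes 4 rose and 5 fell (4 and 7 adjusted over the list alone; list adjusted p = 0.226). The cyclin Ccnd1 fell by 0.83 (SE 0.09) and the proliferation marker Mki67 by 0.51 (SE 0.10). Of 20 p53 and apoptosis genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone; list adjusted p = 0.226), including Trp53inp1 at 0.50 (SE 0.10). Wnt targets and inhibitors split, with 5 of 23 higher and 4 lower (6 and 7 adjusted over the list alone; list adjusted p = 0.580).

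The second comparison asked the same of NSCs. The radial glia transcription factor Pax6 fell from 2747 ± 149 to 156 ± 110 (-4.33, SE 0.33, adjusted p = 2.02e-06), and Olig2, a factor of ventral progenitors and oligodendrocytes, from 1131 ± 325 to 31.7 ± 20.0 (-5.22, SE 0.36, adjusted p = 1.08e-06). Wnt8b, a Wnt ligand of the dorsomedial forebrain, fell from 5198 ± 695 to 43.4 ± 17.2 (-6.92, SE 0.21, adjusted p = 2.88e-09), and the proneural factor Neurog2 from 492 ± 96.3 to 10.3 ± 6.25 (-5.55, SE 0.39). The imprinted RNA H19 rose from 480 ± 145 to 24456 ± 14109 (5.59, SE 0.32, adjusted p = 2.47e-07), and Pou5f1 from 341 ± 72.9 to 2347 ± 986 (2.74, SE 0.24, adjusted p = 5.68e-06). Of 17744 genes tested, 6698 passed, 3236 higher and 3462 lower in TKO, of which 1040 and 1240 changed by at least 2-fold. With equal totals the balance turned, to 3655 higher and 3087 lower, and without chromosomes 8, 11 and distal 6 it was 2088 and 3016. The first principal component (64.1% of variance) separated the genotypes.

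Strc rose in NSCs too, from 3 reads summed over the WT libraries to 8621 over the TKO libraries, a ratio of 3951 (95% counting interval 1358 to 19261, or 824 to 24605 if both mates of each pair were counted). Gzme, a granzyme gene, had 0 reads in WT NSCs and was at least 45.0-fold higher in TKO. Cyct, the testis cytochrome c, rose by 6.52 (SE 1.03), the keratin Krt15 on chromosome 11 by 6.11 (SE 0.96), Gdf3, of the TGF-beta family on distal 6, by 5.69 (SE 0.93), and the protease inhibitor Serpinb2 by 5.67 (SE 0.99). Clca3a1 rose from 16.6 ± 8.26 to 718 ± 10.04 (5.45, SE 0.42), and the X-linked antigen genes Trap1a and Fmr1nb by 5.36 (SE 0.96) and 5.22 (SE 0.72). In the other direction, Vxn, which promotes neuronal differentiation, and Lrtm1 had 0 reads in TKO and were at least 54.4-fold and 49.8-fold lower. Counted as read pairs, a setting chosen after seeing the data, the bounds were 22.5 for Gzme, 27.2 for Vxn and 24.9 for Lrtm1. Mlc1, a membrane protein of astrocytes, fell from 3252 ± 90.9 to 32.8 ± 13.3 (-6.64, SE 0.21, adjusted p = 3.56e-09), and Ptgds, the prostaglandin D synthase, from 512 ± 68.5 to 6.66 ± 1.62 (-6.07, SE 0.32). Cyp24a1, which degrades vitamin D, changed by -5.88 (SE 0.72), Adgra1 by -5.74 (SE 0.83), Minar2 by -5.59 (SE 0.82) and Fam181a by -5.41 (SE 0.63).

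Of 24 neural stem and radial glia genes, 18 fell and 1 rose in TKO NSCs (18 and 1 adjusted over the list alone; list adjusted p = 1.53e-08, and adjusted p = 0.388 with an estimated correlation). Nes fell from 62006 ± 4149 to 29233 ± 3442 (-1.09, SE 0.08, adjusted p = 1.47e-06), Sox2 from 15340 ± 1027 to 7592 ± 1362 (-1.02, SE 0.10), Sox1 from 8100 ± 1288 to 1986 ± 133 (-2.02, SE 0.11) and the fatty acid binding Fabp7 from 17278 ± 3120 to 5048 ± 1870 (-1.81, SE 0.19). The glutamate transporter Slc1a3 fell from 4132 ± 336 to 825 ± 16.8 (-2.32, SE 0.09), and Ednrb and Ptprz1 changed by -2.22 (SE 0.22) and -2.15 (SE 0.15). Of 19 astroglial genes, 1 rose and 12 fell (2 and 12 adjusted over the list alone; list adjusted p = 0.000278, and adjusted p = 0.388 with an estimated correlation). The chaperone Clu fell from 10779 ± 997 to 722 ± 154 (-3.91, SE 0.12) and the gliogenic factors Nfix and Nfia changed by -1.86 (SE 0.09) and -1.58 (SE 0.08). Gfap, the astrocyte filament, fell from 58.0 ± 22.0 to 10.8 ± 4.22 (-2.31, SE 0.57, adjusted p = 0.00778), whereas S100b (adjusted p = 0.873) and Tubb3 (adjusted p = 0.921) did not pass. Of 13 oligodendroglial genes, 2 rose and 3 fell (3 and 3 adjusted over the list alone; list adjusted p = 0.977). Olig1 changed by -2.68 (SE 0.20) and Myrf, a myelin regulator, by 2.13 (SE 0.24). The median (0.23) and the test of this list were positive and its mean negative (-0.29). Neuronal genes went both ways, with 6 of 26 higher and 7 lower (6 and 8 adjusted over the list alone; list adjusted p = 0.848). The neurofilaments Nefm and Nefl rose by 2.89 (SE 0.14) and 2.79 (SE 0.21), and the glutamate transporter Slc17a6 changed by -1.81 (SE 0.34).

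Of 15 dorsoventral patterning genes, 1 rose and 10 fell (1 and 11 adjusted over the list alone; list adjusted p = 0.00508, and adjusted p = 0.585 with an estimated correlation). The dorsal factor Msx1 fell from 1072 ± 162 to 35.1 ± 5.52 (-4.89, SE 0.21), and Nkx6-2 changed by -2.44 (SE 0.43). Of 16 forebrain genes, 6 rose and 7 fell (6 and 7 adjusted over the list alone; list adjusted p = 0.734). Fezf1 fell from 4276 ± 198 to 342 ± 44.8 (-3.65, SE 0.10) and Otx1 changed by -3.19 (SE 0.15), whereas Nkx2-1, of the ventral forebrain and hypothalamus, rose from 405 ± 138 to 4256 ± 1424 (3.40, SE 0.25). Of 21 mid-hindbrain and spinal genes, 9 rose and 3 fell (9 and 3 adjusted over the list alone; list adjusted p = 0.171). Pax2, of the midbrain-hindbrain boundary, stood at -3.31 (SE 0.14) and Hoxb4 on chromosome 11 at 3.11 (SE 0.49). Wnt targets and inhibitors were mostly lower, 14 of 23 falling and 5 rising (14 and 6 adjusted over the list alone; list adjusted p = 0.00524, and adjusted p = 0.388 with an estimated correlation). The ligand Wnt7b fell from 8425 ± 480 to 368 ± 159 (-4.58, SE 0.19), and Notum, a secreted Wnt inhibitor, changed by -3.88 (SE 0.27). Wnt3a went from 188 reads summed over WT to 2 over TKO, 69.5 times lower (18.6 to 566, or 11.9 to 2715 as read pairs), and the inhibitor Dkk1 rose by 3.79 (SE 0.63). Of 27 cell cycle genes, 4 rose and 18 fell (5 and 18 adjusted over the list alone; list adjusted p = 0.00277, and adjusted p = 0.585 with an estimated correlation). Ccnd1 fell from 24464 ± 1784 to 5223 ± 5.14 (-2.23, SE 0.07) and the cell cycle inhibitor gene Cdkn2a rose by 1.05 (SE 0.13).

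Of 21 naive and core pluripotency genes, 12 rose and 0 fell in TKO NSCs (12 and 0 adjusted over the list alone; list adjusted p = 0.000278, and adjusted p = 0.585 with an estimated correlation). The RNA-binding Lin28a rose from 193 ± 29.9 to 1992 ± 703 (3.33, SE 0.22), Sall4 by 3.15 (SE 0.21), Utf1 by 3.45 (SE 0.31), and Dppa2, with 0 reads in WT, was at least 14.4-fold higher (7.22-fold as read pairs). Nanog rose by 2.39 (SE 0.48), lost without TKO replicate 1 (adjusted p = 0.0655, the highest over its alternatives). All 11 primed epiblast genes passed, 7 higher and 4 lower (7 and 4 adjusted over the list alone; list adjusted p = 0.734). Dnmt3b rose from 537 ± 85.0 to 2814 ± 991 (2.35, SE 0.19) and Fgf15 changed by -2.97 (SE 0.31). In the methylation machinery 4 of 17 genes rose and 4 fell (4 and 6 adjusted over the list alone; list adjusted p = 0.977). Dnmt3l rose by 4.36 (SE 0.61) and Dnmt3a by 0.45 (SE 0.07). The mean of the list was above 0 (0.33) and the median (-0.09) and test below it. Dnmt1 changed by -0.19 (SE 0.06, adjusted p = 0.0348), a call lost without any 1 of WT replicates 1 and 3 and TKO replicates 1 and 2, among other settings, with adjusted p of up to 0.150 over its alternatives. Of 8 germline genes measured, 4 rose and 1 fell (6 and 1 adjusted over the list alone; list adjusted p = 0.0831). The X-linked homeobox gene Rhox5 rose by 3.52 (SE 0.40) and Tex19.1, with 0 reads in WT, was at least 13.6-fold higher (6.78-fold as read pairs). Imprinted genes rose on the whole, 20 of 31 higher and 6 lower (20 and 6 adjusted over the list alone; list adjusted p = 0.000278, and adjusted p = 0.388 with an estimated correlation). Beside H19, Magel2 rose by 2.64 (SE 0.20), Zim1 changed by -2.10 (SE 0.22), and Grb10 changed by -3.53 (SE 0.68), lost under a robust fit (adjusted p = 0.132, the highest over its alternatives). The TKO lines differed: Grb10 stood at -5.28 without TKO replicate 1 and at -1.79 without TKO replicate 2.

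Of 14 neural crest genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone; list adjusted p = 0.0222, and adjusted p = 0.585 with an estimated correlation). The neurotrophin receptor Ngfr on chromosome 11 rose by 3.60 (SE 0.31) and Ets1 by 2.03 (SE 0.10). Of 18 mesoderm genes, 9 rose and 2 fell (10 and 3 adjusted over the list alone; list adjusted p = 0.0342, and adjusted p = 0.733 with an estimated correlation). Meox1, a somite factor on chromosome 11, rose by 4.22 (SE 0.39) and the cardiac actin Actc1 by 2.91 (SE 0.49). Of 14 trophoblast and epithelial genes, 8 rose and 1 fell (9 and 1 adjusted over the list alone; list adjusted p = 0.0300, and adjusted p = 0.585 with an estimated correlation). E-cadherin (Cdh1) rose from 343 ± 33.9 to 3260 ± 1991 (3.10, SE 0.29) and Krt8 by 2.19 (SE 0.20). Fibroblast and mesenchyme genes split, 10 of 18 higher and 6 lower (10 and 6 adjusted over the list alone; list adjusted p = 0.293). The smooth muscle actin Acta2 fell from 88104 ± 14259 to 8755 ± 2830 (-3.36, SE 0.17) and Tagln changed by -2.07 (SE 0.11), while Mgp on distal 6 and Twist2 rose by 2.89 (SE 0.28) and 2.28 (SE 0.36). Of 20 p53 and apoptosis genes, 9 rose and 3 fell (11 and 3 adjusted over the list alone; list adjusted p = 0.0175, and adjusted p = 0.850 with an estimated correlation). Trp53 itself, on chromosome 11, rose by 0.74 (SE 0.08), lost with chromosomes centred (adjusted p = 0.0583, the highest over its alternatives), and its targets Trp53inp1 and Phlda3 rose by 0.76 (SE 0.10) and 0.69 (SE 0.09). In all 11 of the lists tested in NSCs were called by camera, and 6 without TKO replicate 1. Of these 11, fry called 9, with trophoblast and epithelial genes (adjusted p = 0.0773) and p53 and apoptosis genes (adjusted p = 0.161) missing the threshold. It also called germline genes, higher on balance (adjusted p = 0.000807), and forebrain genes, lower on balance (adjusted p = 0.0343). Chromosome 11 held 23.9% of the higher calls, and chromosomes 8, 11 and distal 6 together 20.6% of calls and 14.0% of tested genes.

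**Figure D3:**
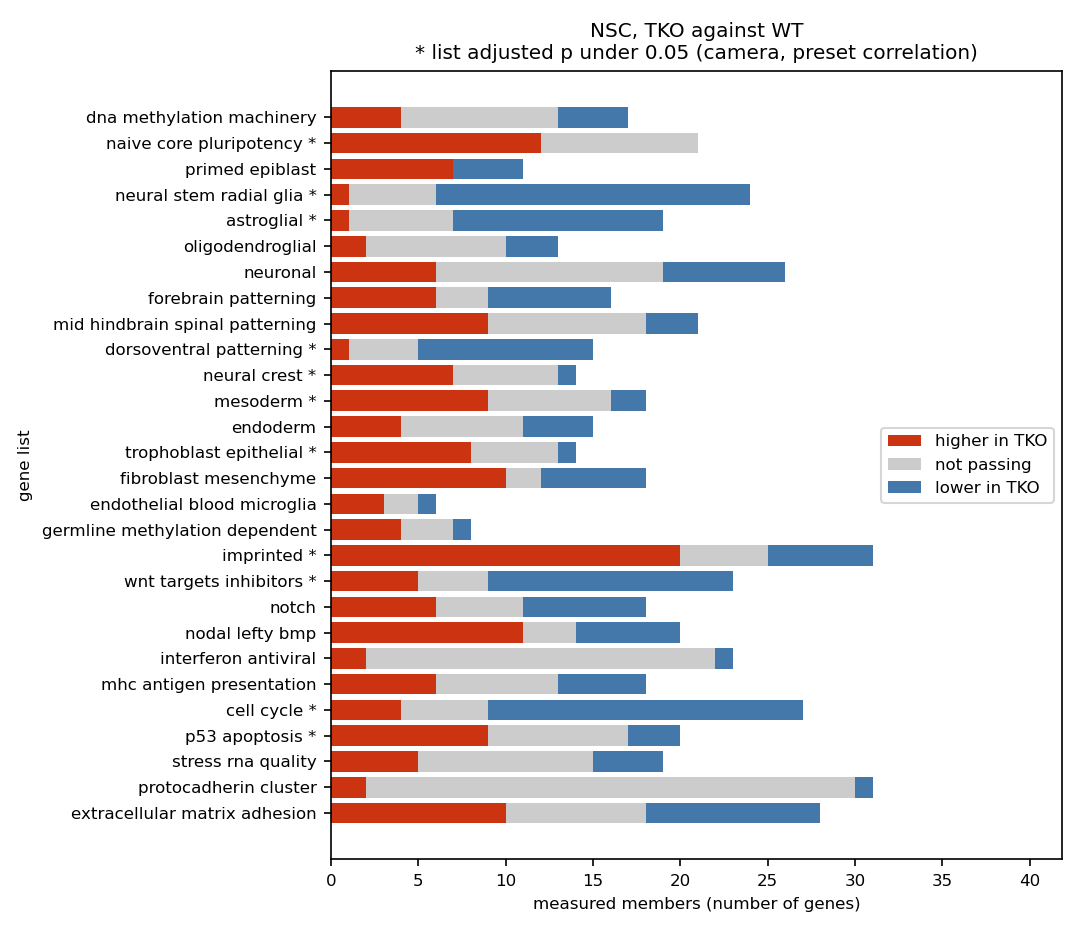
Number of measured genes of each list (x axis, genes) that were higher in TKO NSCs (red), lower (blue) or did not pass (grey), with 3 WT and 2 TKO lines; asterisks mark lists with a camera adjusted p under 0.05 at the preset correlation. Neural stem and radial glia genes were mostly lower (18 of 24), and imprinted genes mostly higher (20 of 31).

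Whether the TKO effect differed between NSCs and ESCs was tested directly. The effect was higher in NSCs for Clca3a1 by 7.68 (SE 1.53), Cyp26a1 by 5.86 (SE 0.57), Slc15a2 by 5.76 (SE 0.91), H19 by 5.67 (SE 0.41, adjusted p = 8.30e-07) and Dppa2, whose fitted difference of 5.24 rests on 0 reads in WT NSCs. It was lower for Lrtm2, on distal 6, at -6.26 (SE 0.94), Megf11, an EGF-repeat gene, at -6.04 (SE 0.47, adjusted p = 1.68e-06), and the lipase family gene Pnpla3 at -5.81 (SE 0.56). Ecrg4 stood at -6.39 (SE 1.48), lost with DESeq2 (adjusted p = 0.0737, the highest over its alternatives), and Zbp1, a sensor of viral nucleic acid, had 0 reads in TKO NSCs while it rose by 1.68 in ESCs, a call lost without TKO ESC replicate 2 (adjusted p = 0.165, the highest over its alternatives). The interaction passed for 3177 of 15381 genes, 1669 higher and 1508 lower in NSCs, of which 721 and 697 by at least 2-fold, and for 2092 without the TKO NSC library of replicate 1. With equal totals 1966 were higher and 1322 lower, and without chromosomes 8, 11 and distal 6 the balance turned, to 1152 and 1359.

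Calls in both cell types overlapped in direction. Among 15369 genes tested in both, 683 were higher in TKO in each (231 from independent lists, Fisher's exact test, odds ratio 7.02, 95% interval 6.19 to 7.97, adjusted p = 2.22e-204) and 421 were lower in each (233 from independent lists, odds ratio 2.46, 2.16 to 2.80, adjusted p = 3.07e-40). Opposite calls were fewer than from independent lists, 138 (236) for higher in ESCs and lower in NSCs and 170 (228) for the converse (odds ratios 0.507 and 0.683, adjusted p = 5.76e-15 and 4.70e-06). At 2-fold or more the direction turned, to 18 (9.61) and 23 (11.9), with adjusted p = 0.0107 and 0.00315. Without chromosomes 8, 11 and distal 6, a setting chosen after seeing the data, both calls were lost, at 110 (123) and 98 (107), with adjusted p = 0.233 and 0.357, and likewise with chromosomes centred (adjusted p = 0.628 and 0.147). Without the 3 regions 196 genes were higher in both (86.9 from independent lists, odds ratio 3.16) and 286 lower (152 from independent lists, odds ratio 2.69). The libraries of both cell types carry the same line codes, so the lists are not from separate sets of lines, and genes are not independent replicates.

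NSCs were also compared with ESCs within each genotype, to ask how the differentiation program ran. Only the 15381 genes listed in both cell types entered, of 17036 listed in ESCs and 17771 in NSCs. Genes listed in NSCs alone are therefore absent from the induced genes below, and genes listed in ESCs alone from the repressed ones. This was uneven between lists: 23 of 24 neural stem and radial glia genes measured in NSCs entered, but 7 of 16 forebrain genes. In WT, all 21 naive and core pluripotency genes fell, with a median log2 change of -8.45. Of 23 neural stem and radial glia genes, 20 rose and 1 fell in WT (median 3.19). In TKO the same lists gave 21 lower (median -6.54) and 18 higher with 2 lower (median 1.99). Of 15381 genes, 11584 changed in WT (5815 higher and 5769 lower in NSCs) and 10798 in TKO (5439 and 5359), with 9412 changed in the same direction in both. Of the 1933 genes that rose at least 4-fold in WT, 46.4% (44.2 to 48.7%) were lower and 16.9% (15.2 to 18.6%) higher in TKO NSCs than in WT NSCs. Of 1277 genes that fell at least 4-fold in WT and were tested in NSCs, 38.4% (35.7 to 41.1%) were higher and 3.76% (2.78 to 4.95%) lower in TKO NSCs. Genes that changed under 2-fold in WT were higher in 17.1% and lower in 16.8% of 7970 cases. The same WT NSC libraries enter both comparisons, so part of these shares may come from them. The median log2 TKO effect was -0.33 for the induced and 0.63 for the repressed genes, against -0.018 to -0.00014 and 0.015 to 0.055 in 20 simulations with unchanged TKO groups. In the simulations at most 0.103% of the induced and 0% of the repressed genes were called in either direction. With so few calls the adjusted threshold is stricter there than in the data.

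Promoter contacts in NSCs were compared between a single library per genotype, without replicates. The lists held 59754 loops in WT and 58145 in TKO, a ratio of 0.973 (exact 95% interval 0.962 to 0.984, counting error only), with a median distance of 212 kb between anchors in each. Of these, 26.0% in WT and 24.2% in TKO were listed in both directions, leaving 51990 and 51122 distinct pairs. The intervals of loop numbers and shares given here count both listings of a pair, and so are too narrow. Of the WT loops, 30.8% (30.4 to 31.2%) had the same pair of fragments in TKO, and of the TKO loops 31.4% (31.0 to 31.8%) were found in WT. The share rose with the score, from 18.9% of WT loops scored 5 to 6 to 83.3% of those scored at least 15, and from 20.0% to 83.4% for TKO loops, and with anchors matched within 10 kb it was 56.0% and 57.5%. Loops first anchored on chromosome 11 were 1.60 times as many in TKO (1.54 to 1.65) and those of distal 6 were 1.74 times as many (1.62 to 1.87), against ratios of 0.794 to 0.957 on the other 19 chromosomes or parts.

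**Figure D4:**
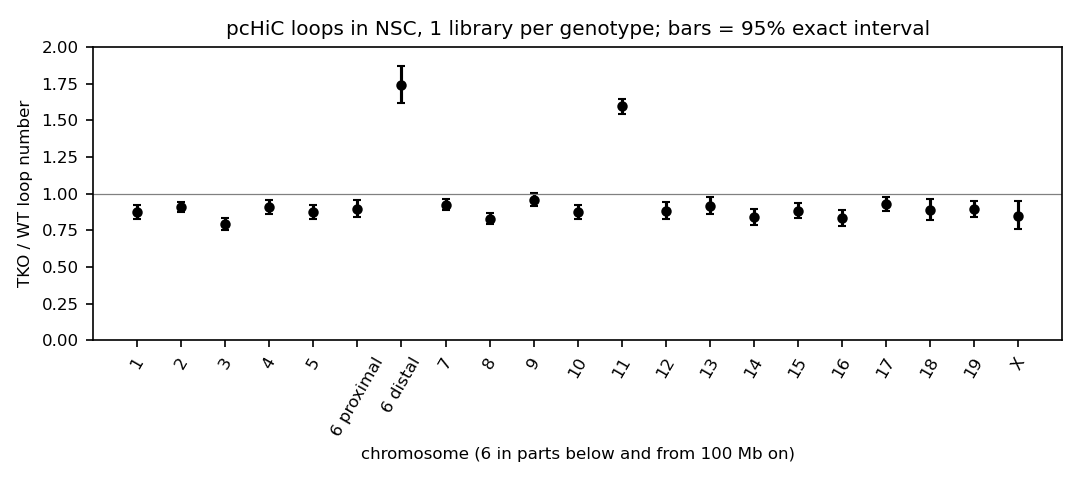
Ratio of the number of pcHiC loops in TKO to WT NSCs (y axis) by chromosome of the first anchor (x axis; chromosome 6 in parts below and from 100 Mb on); points are ratios between 1 library per genotype and bars their exact 95% intervals, which cover counting error only. Pairs listed in both directions enter with both listings, so the bars are too narrow. Chromosome 11 (1.60) and distal 6 (1.74) lay above 1, and the other 19 parts between 0.794 and 0.957.

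Loop numbers at neural and pluripotency genes went both ways. Fragments at Olig1 had 18 loops in WT and 0 in TKO, those at Olig2 had 8 and 2, at Fabp7 7 and 0, at Ccnd1 22 and 4, at Mlc1 14 and 6, at Sox1 10 and 6 and at Pax6 4 and 2, and transcripts of these genes fell in TKO NSCs. Sox2 (16 and 24), Nes (5 and 8) and, on chromosome 11, Gfap (12 and 26) fell in expression with more loops listed in TKO. Among genes that rose, Dnmt3l had 6 loops in WT and 15 in TKO, Pou5f1 0 and 3, Nkx2-1 5 and 9, and, on chromosome 11, Ngfr 0 and 7. Of the 64 named genes that fell and had a loop in either list, 40 had fewer, 19 more and 5 equally many in TKO, and of 68 that rose, 30 had fewer, 28 more and 10 equally many. The largest gains were at Eif4a1 (31 to 77), Cenpx (7 to 35) and Polg2 (2 to 28) on chromosome 11 and at Atn1 and Phb2 (each 13 to 40) on distal 6. The largest losses were at Rrnad1 (43 to 13) on chromosome 3, at Mrpl34 (46 to 17), Edc4 (41 to 14) and Nutf2 (42 to 16) on chromosome 8, and at the ribosomal protein gene Rpl13a (71 to 45) on chromosome 7. A fragment that holds ends of 2 genes counts for both. The neighbours Atn1 and Phb2, and Edc4 and Nutf2, may therefore share loops and need not be separate gains or losses. A gene listed with 0 loops had none scored at least 5.

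Across 12546 genes with a loop in either list, the 4771 with more loops in TKO had a median log2 fold change of 0.07 in TKO NSCs, above all of 10000 random lists matched on expression (-0.0088 to 0.0377). The 6010 genes with fewer loops had a median of -0.02, below all random lists (-0.0082 to 0.0273), and the 1765 with equally many stood at -0.0055, at the 4.82 percentile. Spearman's rho between the differences in loops and in expression was 0.118 across genes, which are not independent replicates. Without chromosome 11 and distal 6, chosen after seeing the data, genes with more loops had a median of -0.0084, at the 99.8 percentile of their random lists, genes with fewer loops -0.04, at the 0.43 percentile, and rho was 0.0533.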

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

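The interaction test was planned, and both tests of explanations given here were chosen only after the result was seen.

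The TKO effect differed between NSCs and ESCs for 3177 genes by the interaction test of limma. Of 40 genes named in both cell types, 27 passed. Genes named for the size of their interaction pass by that rule, and with them 36 genes are listed here. Other genes named in only 1 cell type were not counted. Of the 36, 22 had a higher and 14 a lower effect in NSCs (highest adjusted p = 0.0282). Numbers here are the NSC minus the ESC log2 effect. Among pluripotency and methylation genes it was 2.56 for Pou5f1, 1.92 for Nanog, 5.24 for Dppa2, 2.44 for Dnmt3b, 3.65 for Tex19.1, 0.70 for Tet1 and 0.70 for Tet2. Nodal stood at 1.86, its inhibitor Lefty1 at 2.69 and the related Gdf3 at 5.07. Neural genes went lower in NSCs: Pax6 -4.43, Olig2 -4.89, Sox1 -2.57, Sox2 -1.32, Nes -0.43, Fabp7 -1.87, Gfap -3.61 and Clu -4.50. The neuronal Nefm (3.57), Nefl (3.52), Tubb3 (0.59) and the protocadherin Pcdhgc3 (0.94) went the other way, as did Actc1 (4.48), Krt8 (3.19), Gbp2 (2.60), Chac1 (2.58), H19 (5.67), Clca3a1 (7.68), Cyp26a1 (5.86) and Slc15a2 (5.76). Lower effects were found for Ccnd1 (-1.40), Zbp1 (-5.95), Megf11 (-6.04), Lrtm2 (-6.26), Pnpla3 (-5.81) and Ecrg4 (-6.39). For Dppa2, Tex19.1 and Zbp1 an NSC group had 0 reads, so that the fitted difference depends on the pseudocount and is no bound. Sox1 and Tubb3 lie on chromosome 8, Gdf3, Nanog and Lrtm2 on distal 6, and Gfap and Tex19.1 on chromosome 11, parts whose medians moved in TKO. Cyp26a1 (-2.62 in ESCs and 3.24 in NSCs), Krt8 (-1.01 and 2.19), Chac1 (-0.90 and 1.68) and Gbp2 (-0.97 and 1.63) fell in TKO ESCs and rose in TKO NSCs.

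The lists of pluripotency, neural crest, mesoderm and trophoblast genes were called higher in TKO NSCs by camera, and none of these calls held with an estimated correlation (adjusted p = 0.585 to 0.733). Endoderm (adjusted p = 0.734), fibroblast (0.293) and endothelial (0.831) lists were not called. ESCs left in those cultures with their expression unchanged would bring all their transcripts in 1 proportion. Over the 12 raised pluripotency genes, the excess over WT NSCs was taken as a share of the TKO ESC level. It differed 30.4-fold in the library where it differed least, from 4.07% for Lin28a to 0.134% for Dppa5a. That argues against unchanged leftover ESCs as the only source of these transcripts, while a contribution from them stays open. Leftover cells whose expression had shifted in culture are not held to 1 proportion, so the shares cannot decide on them. A smaller neural share with all other lineages raised alike would leave few of their markers lower. Of the 54 called members of 6 lineage lists, 14 were lower (25.9%, exact 95% interval 14.96 to 39.7%), Acta2 and Kdr among them. Over all genes, 3462 of 6698 calls were lower. Acta2 averaged 88104 in WT NSCs, above Nes at 62006, so a lower member need not mark another lineage. The count therefore cannot decide on a smaller neural share. Cells stalled at an intermediate stage, a change in which other cells arise, or a direct effect of TET loss on these genes may each account for the pattern, and none of them was tested.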

How the results depend on the processing

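Leaving out or centring chromosomes 8, 11 and distal 6 was chosen only after the results were seen, as were dividing reads by 2 and counting read pairs. All other settings were planned. For RNA-seq, values without the 3 regions are also without the genes that have no position. Of 5077 values of named genes and lists and 158 that answer a comparison, 10 and 4 could not move: no interaction gene lay under the filter, identical anchors gave the same loops, and rho uses no limit on loops. Of the other 5067, 4763 kept direction and side of the threshold, 280 missed the threshold, 15 turned sign and 9, bounds and intervals of read ratios, moved by over 1.5 times with read pairs. Of the other 154 values that answer a comparison, 108 held, 39 moved, 4 missed the threshold and 3 turned direction. The settings with the most losses were without TKO ESC replicate 2 (39), without TKO NSC replicate 1 (27) and with all 10 libraries in one fit (24). In fits that leave an arm with 1 library, that library is assumed to vary like the others. With 1 library left out, the effect of 17 of 101 called named genes in ESCs and of 35 of 129 in NSCs moved by over 1.5-fold. Except where given, the cause of the changes below was not tested.

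The ESC count of 2437 became 1306 without the 3 regions, 1588 with chromosomes centred, 454 at 2-fold or more, and 1066 to 2275 with 1 library left out (2384 with edgeR and 2873 with DESeq2). The NSC count of 6698 was 2280 at 2-fold or more, and 4787 to 5888 with 1 library left out. The interaction count of 3177 was 1418 at 2-fold or more, and 2092 to 3308 with 1 library left out. The WT and TKO libraries share only replicate numbers, whose deviations correlated within 0.072 of 0, and a replicate block gave 1912 calls in ESCs and 6275 in NSCs. WT replicate 3 has no TKO library of its number, so with that block it does not enter the genotype effect. A line block in the comparisons of NSCs with ESCs moved no call count by over 1.5 times (the interaction count was 2930).

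Genes higher in both cell types numbered 44 at 2-fold or more, 196 without the 3 regions and 256 with chromosomes centred, and genes lower in both 40 at 2-fold or more. The odds ratios of opposite calls, 0.507 and 0.683, turned to 2.00 and 2.07 at 2-fold or more, and missed the threshold at 0.860 and 0.896 without the 3 regions and at 0.9505 and 0.848 with chromosomes centred. Lists called in ESCs numbered 0 with an estimated correlation, 5 with the replicate block, 2 with chromosomes centred and 1 to 5 with 1 library left out, and in NSCs 0 with an estimated correlation and 6 to 12 with 1 library left out. Of the genes induced in NSCs, 39.6% were lower in TKO at a 2-fold limit, 52.9% at 8-fold and 49.6% without the 3 regions, where 14.9% were higher. Of the repressed genes 31.3% and 44.4% were higher and 7.78% and 2.38% lower at the 2-fold and 8-fold limits.

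Anchors matched within 10 kb gave 56.0% of WT and 57.5% of TKO loops found in the other list. The upper part of the scores gave 31.6% and 32.6% with a TKO to WT ratio of 0.952, and without chromosome 11 and distal 6 these were 29.2%, 32.5% and 0.887. Genes with at least 2 more loops in TKO had a median of 0.0982. Without chromosome 11 and distal 6 the medians were -0.0407, -0.0382 and -0.0084 for fewer, equal and more loops, the last turning sign, and rho was 0.0533.

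With chromosomes centred, Nanog (-0.0405) and Ccng1 (-0.0105) turned sign in ESCs, which follows from their place on distal 6 and chromosome 11. None of the other genes that turned sign had passed. Fabp7 in ESCs was at -0.0243 with edgeR and between -0.29 and 0.27 with 1 library left out, and Sox1 between -0.27 and 1.08. In NSCs Tubb3 was at 0.0218 with equal totals, 0.00014 with equal upper quartiles, 0.0104 when quantile normalized, 0.0114 with chromosomes centred and 0.129 with the replicate block. With 1 library left out, Tubb3 ranged from -0.11 to 0.13, Tet2 from -0.0756 to 0.36 and S100b from -0.88 to 1.38, crossing 0 without WT replicate 2 or 3 or TKO replicate 2. Of 50 simulated genes each changed by 1.5-fold, 52% were recovered in ESCs and 58% in NSCs. The simulations changed far fewer genes than were called in the data, which makes the adjusted threshold stricter in them. The share of small changes missed in the data is therefore not known.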

Other observations

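The lists below were planned, and the tests of chromosomes 6, 8 and 11 were chosen only after the results were seen.

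No list of Nodal and BMP, Notch, immune or adhesion genes was called in NSCs, though members of each passed. Of 20 Nodal, Lefty and BMP genes, 11 rose and 6 fell in TKO (11 and 6 adjusted over the list alone; list adjusted p = 0.722). The BMP inhibitor Grem1 rose from 39.2 ± 8.32 to 166 ± 45.7 (2.05, SE 0.38). Of 18 Notch genes, 6 rose and 7 fell (6 and 8 adjusted over the list alone; list adjusted p = 0.977). The receptor Notch2 fell from 9559 ± 452 to 4232 ± 442 (-1.18, SE 0.08), while median (-0.03) and mean (-0.02) were below 0 and the test above it. Of 28 extracellular matrix and adhesion genes, 10 rose and 10 fell (10 and 11 adjusted over the list alone; list adjusted p = 0.703). The brain proteoglycans Bcan and Cspg5 changed by -3.09 (SE 0.30) and -2.73 (SE 0.09), and the integrins Itgb3, on chromosome 11, and Itga1 rose by 2.45 (SE 0.24) and 1.83 (SE 0.13). Antigen presentation split as well, with 6 of 18 higher and 5 lower (7 and 5 adjusted over the list alone; list adjusted p = 0.791). The immunoproteasome subunit Psmb8 changed by 2.06 (SE 0.31) and the class I gene H2-K1 by -1.21 (SE 0.10). Of 23 interferon and antiviral genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone; list adjusted p = 0.848). Gbp2 rose by 1.63 (SE 0.26) and Zbp1, with 0 reads in TKO, was at least 6.60-fold lower (3.30-fold as read pairs). Here median (0.06) and test were above 0 and the mean (-0.14) below it. Of 19 stress and RNA quality genes, 5 rose and 4 fell (5 and 4 adjusted over the list alone; list adjusted p = 0.987). Trib3 stood at 2.08 (SE 0.33), Chac1 at 1.68 (SE 0.29) and Gadd45b at -1.05 (SE 0.15), with median (0.03) and mean (0.11) above 0 and the test below it. Among 15 endoderm genes 4 rose and 4 fell (6 and 4 adjusted over the list alone; list adjusted p = 0.734), with the chemokine receptor Cxcr4 at -1.50 (SE 0.11). Among 6 endothelial, blood and microglia genes 3 rose and 1 fell (3 and 2 adjusted over the list alone; list adjusted p = 0.831), with Emcn at 3.01 (SE 0.22) and the VEGF receptor Kdr at -2.51 (SE 0.18). Of 31 clustered protocadherins, 2 rose and 1 fell (1 and 1 adjusted over the list alone; list adjusted p = 0.848), Pcdhac2 at -2.57 (SE 0.31). None of the 3 measured genes of the 2-cell-like list passed (0 adjusted over the list alone), too few for a list test.

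In ESCs, members of most of these groups passed the test as well. Of 20 Nodal, Lefty and BMP genes, 4 rose and 2 fell (5 and 4 adjusted over the list alone; list adjusted p = 0.791), with Lefty1 down by 0.67 (SE 0.11), lost with all 10 libraries in one fit (adjusted p = 0.161, the highest over its alternatives). Of 18 Notch genes 1 rose and 3 fell (2 and 4 adjusted over the list alone; list adjusted p = 0.901), the ligand Jag2 at -0.69 (SE 0.12). Of 28 matrix and adhesion genes 6 rose and 4 fell (8 and 4 adjusted over the list alone; list adjusted p = 0.411), and of 26 interferon genes 2 rose and 1 fell (3 and 1 adjusted over the list alone; list adjusted p = 0.580), Oas1a at 0.99 (SE 0.19) and Gbp2 at -0.97 (SE 0.20). Of 15 endoderm genes 4 rose and 2 fell (5 and 2 adjusted over the list alone; list adjusted p = 0.411), with the matrix protein Sparc on chromosome 11 up by 0.99 (SE 0.10). Of 14 astroglial genes 2 rose and 1 fell (2 and 1 adjusted over the list alone; list adjusted p = 0.791), and the lipid carrier Apoe fell from 20968 ± 2437 to 12491 ± 3598 (-0.77, SE 0.13, and -0.47 without TKO replicate 2). Of 13 oligodendroglial genes 2 rose and 1 fell (3 and 2 adjusted over the list alone; list adjusted p = 0.580), with Cnp on chromosome 11 at 1.04 (SE 0.17) and Mobp at -1.12 (SE 0.18). Of 12 neural crest genes Erbb3 rose by 1.05 (SE 0.11) and none fell (1 and 0 adjusted over the list alone; list adjusted p = 0.491). Among 10 endothelial, blood and microglia genes 2 rose and 0 fell (2 and 1 adjusted over the list alone; list adjusted p = 0.580). Of 17 antigen presentation and 18 fibroblast genes 1 each rose and 0 fell (0 and 0 adjusted over the list alone for both; list adjusted p = 0.779 and 0.657), and none of 8 protocadherins passed (0 adjusted over the list alone; list adjusted p = 0.226). Of 11 genes of the 2-cell-like list 0 rose and 2 fell (0 and 3 adjusted over the list alone; list adjusted p = 0.360). Zscan4a, of the latter, was at -3.44 (SE 0.80), lost without WT replicate 3 or TKO replicate 2, with adjusted p of up to 0.0757. Medians were above 0 and means below it for the endoderm (0.38 and -0.13), endothelial (0.15 and -0.12) and Nodal (0.01 and -0.12) lists, whose tests were above 0.

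Strc lies at 121363248 to 121381370 of chromosome 2 (mm10). The lowest TKO library of either cell type had 2752 normalized counts of Strc and the highest WT library 4.02.

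Genes of chromosome 11 and distal 6 were higher in TKO ESCs and NSCs. A few strongly changed genes do not account for it, since of genes with a mean of at least 100, at least 85.6% on chromosome 11 and 81.9% on distal 6 were higher in each cell type, nor does scaling, since no other chromosome except 8 had a median farther from 0 than -0.11 in any TKO library. Extra copies of both regions in the TKO lines may account for it: relative to the other chromosomes, pcHiC loops in TKO NSCs were 1.80 times as many on chromosome 11 and 1.96 times on distal 6, against 0.895 to 1.08 elsewhere. That rests on 1 library per genotype, and DNA copies were not measured here. An effect of TET loss on transcription of whole regions was not tested and stays open, as does the lower chromosome 11 median of TKO ESC replicate 1 (0.25).

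Genes of chromosome 8 were lower in TKO ESCs but not in TKO NSCs. If TKO ESCs had a low level, it should rise from ESCs to NSCs in TKO, and the median change there was -0.012 (log2), within the range of the other autosomal parts (-0.25 to 0.24). In WT it was -0.338, outside the range of the others (-0.18 to 0.20), and in the 3 lines -0.37, -0.39 and -0.30. A high level of chromosome 8 in WT ESCs, such as extra copies in a share of the cells would give, is a candidate explanation of the lower calls on chromosome 8. The WT change is not separate evidence, as it largely follows from the TKO change and the differences between genotypes. The explanation assumes that differentiation shifts chromosome 8 no more than the others. It also assumes that the high level was no longer present in the WT NSCs. An effect of genotype on chromosome 8 in ESCs stays open.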
